A study of Homo sapiens with 7 samples.

How the data were processed

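RNA sequencing was carried out on MDA-MB-231 cells, a human triple-negative breast cancer line, transfected with a control siRNA (siCTL, 3 libraries) or with siRNA against DEPDC1 (siDEPDC1, 4 libraries). Per the labels' protocols, the transfection medium was replaced after 8 h and RNA was harvested 2 days after transfection, libraries were made with a TruSeq RNA kit, and paired reads of 100 bases were sequenced. The authors deposited a table of raw counts per Ensembl gene and library, with no pooling and no normalization visible in the values. Per the submitters' processing notes, the genome build was GRCh38 and the tools named were FastQC, STAR 2.7.9a and DESeq2, with no role or order given. The read counter, the annotation release, the strand setting and whether libraries were poly(A)-selected or depleted of ribosomal RNA are not given in the sources used here. A missing strand setting matters for genes that overlap on opposite strands, and the unknown selection matters for transcripts that lack a poly(A) tail. The sequence of the siRNA, and whether it was 1 duplex or a pool, is likewise not given in the sources used here.

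The table held 60675 gene identifiers, of which 42022 had a symbol in the name table used and 58444 were found in GENCODE release 29 (GRCh38), the source of coordinates, transcript GC content, transcript length and 3' UTR sequence. This release may not be the one used to count. Library totals ran from 7690583 to 15360409 counts, and 35823 genes had at least 1 count. Genes were filtered with edgeR's filterByExpr defaults by group, which left 16583. Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, glmQLFit with robust estimation, glmQLFTest, two-sided), with group as the only term and Benjamini-Hochberg adjustment at 0.05. Fold changes are siDEPDC1 over siCTL. Levels are CPM scaled with the TMM factors, given as mean ± SD over libraries, and the error of a log2 fold change is the standard error implied by the quasi-likelihood F statistic. "Lower", "higher", "rose" and "fell" refer to genes past the adjusted threshold.

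The following choices were made before the data were examined. The 22 gene lists covered mitosis, DNA replication and G1/S, homologous recombination and Fanconi repair, p53 targets, apoptosis regulators, NF-kB targets and cytokines, type I interferon response, antigen presentation, endoplasmic reticulum and amino acid stress, cholesterol synthesis and uptake, fatty acid metabolism, glycolysis and hypoxia, nuclear-encoded oxidative phosphorylation, mesenchymal and invasion genes, epithelial genes, YAP/TEAD targets, autophagy and lysosome, immediate early and heat shock genes, replication-dependent histones, cytosolic ribosomal proteins, mitochondrially encoded genes, and markers of other cell types. Each list with at least 5 tested members was tested with camera (limma 3.58.1) at a preset correlation of 0.01, which compares the list with all other genes, adjusted over the 22 lists. The same test with a correlation estimated for each list and the self-contained fry test were alternatives. The rule for named genes took DEPDC1 and its paralog DEPDC1B, then the 10 largest falls and 10 largest rises among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups, and from each list up to 3 called members with the smallest adjusted p plus up to 2 called members that went against the list. Genes without a symbol, or with a clone or pseudogene name, were passed over, which removed 1 gene in each direction. List members named outside this rule were chosen after their values were seen. Some genes that the rule picked are left out of the text. SOD2 and H2AC18 had no match by symbol in the table.

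Results were also computed with DESeq2 size factors in the same edgeR fit, library size alone, no count filter, a filter of at least 50 counts in every library of a group, DESeq2 1.42.0, limma-voom, a replicate block on numbers 1 to 3, the same 6 libraries without the block, thinning to the smallest library, and with each library left out in turn. The removal of a GC and length trend from each library (loess, span 0.4) and the removal of genes that carry the 3' UTR word described with the falls were added after seeing the data. GC content and length were known for 98.9% of tested genes. Camera was also run, after seeing the data, on 12 gene families and on 4 further gene sets, adjusted within each of these collections, and intervals of a set's median are percentiles of bootstrap draws of its members.

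For the 3' UTR word, a single annotated transcript was kept per gene, so a copy in another isoform of the gene would be missed. The 12322 tested genes whose kept transcript had a 3' UTR of at least 50 bases were split at random into 2 parts of 6161 genes. Log2 fold changes were adjusted for 3' UTR length, the 7-base word with the lowest rank score was found in the first part, and its carriers were tested in the other part with 100000 permutations (Python 3.11.15, scipy 1.17.1). Genes whose kept transcript had no such 3' UTR were counted as not searched.

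The edgeR step was tested on simulated data built from the means and totals of these libraries, with 16361 genes past the filter. It recovered 52.4% of 63 genes changed 1.25-fold, 71.2% of 66 changed 1.5-fold and 90.9% of 66 changed 2-fold, and 6 of its 146 calls were false. Few genes were changed there, whereas 34.4% of tested genes were called in the real data. The shares recovered and the false calls therefore need not hold for the real comparison. In that simulation camera called 0 of 20 random lists of unchanged genes. Genes drawn at random need not vary together as members of a real list can. Correlations estimated for the real lists ran from -0.033 (p53 targets) to 0.89 (mitochondrially encoded genes). The simulated lists therefore do not test whether the preset correlation suits the real lists. Pairs of libraries in a group were compared with a chi-square statistic over genes, which was 1.68 to 4.69 times its degrees of freedom. This shows that no library is a second count of another, but not whether the libraries came from separate cultures.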

Results

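Gene expression was measured by RNA sequencing in MDA-MB-231 cells, a triple-negative breast cancer line, 2 days after transfection with control siRNA (siCTL, n = 3 libraries) or siRNA against DEPDC1 (siDEPDC1, n = 4 libraries). A small interfering RNA guides cleavage of the messenger RNA it pairs with, so the series compares cells with and without a lowered DEPDC1 transcript. Totals were 11704246 to 15360409 counts in the siCTL libraries and 7690583 to 13483305 counts in the siDEPDC1 libraries, a difference in means that did not pass an exact two-sided permutation test (p = 0.114, with 0.0286 the smallest value that 3 against 4 libraries allow). Mitochondrially encoded genes took 4.16 ± 0.481% of counts in siCTL and 4.14 ± 0.139% in siDEPDC1 (SD). The first principal component of log2 CPM held 52.1% of the variance and separated the groups. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

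DEPDC1 (ENSG00000024526; GRCh38 chromosome 1, 68474152 to 68497221, minus strand), which encodes a DEP domain protein expressed in dividing cells, was the siRNA target. Its level was 114, 119 and 120 CPM in the siCTL libraries and 15.3, 12.7, 13.4 and 11.9 CPM in the siDEPDC1 libraries. The means were 118 ± 3.20 CPM (SD, n = 3) and 13.3 ± 1.43 CPM (SD, n = 4), so that 11.3% of the transcript was left. Its log2 fold change of -3.15 ± 0.075 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.2e-26) had the smallest p of all tested genes. The paralog DEPDC1B (ENSG00000035499; chromosome 5, 60596912 to 60700190) was at 41.7 ± 1.18 and 36.5 ± 5.28 CPM, a difference that did not pass the test (log2 fold change -0.19, edgeR adjusted p = 0.075). Without siDEPDC1 replicate 2 the paralog passed it, at -0.28 (edgeR adjusted p = 0.015), as it did with no count filter, at -0.21 (edgeR adjusted p = 0.045). ENSG00000233589, annotated on the opposite strand inside the DEPDC1 gene (68479129 to 68483539), had a log2 fold change of -3.52. Whether counting used the strand is not given in the sources used here, so its reads and those of DEPDC1 cannot be separated.

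**Figure D1:**
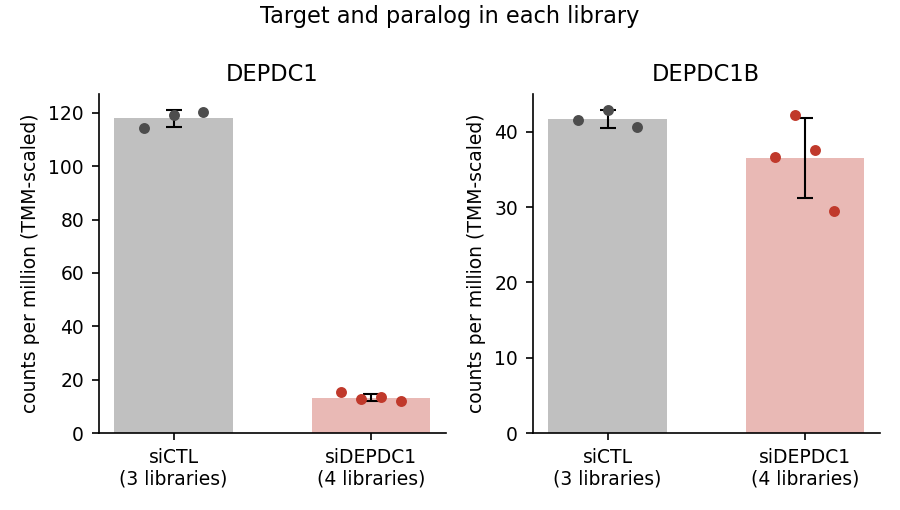
TMM-scaled CPM of DEPDC1 (left) and DEPDC1B (right) in each library (points), with the group mean (bar) and SD (line), for 3 siCTL and 4 siDEPDC1 libraries. DEPDC1 lies between 11.9 and 15.3 CPM in the siDEPDC1 libraries and at 114 CPM or more in the siCTL libraries, while the DEPDC1B values of both groups overlap.

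After DEPDC1 siRNA, 2975 of 16583 tested genes were lower and 2732 were higher, together 34.4% of the genes tested (edgeR quasi-likelihood test, adjusted p under 0.05). Most changes were small, with a median absolute log2 fold change of 0.37 among the called genes, and 215 genes were lower and 220 higher by at least 2-fold. These 2-fold counts were 126 and 54 with the stricter count filter, and 357 genes were lower by at least 2-fold with no count filter. In 6189 tested genes (37.3%) every siDEPDC1 library lay on the same side of every siCTL library, against 5.71% by chance. After DEPDC1, the largest falls named by the rule were in ITGA10, an integrin subunit that binds collagen, from 50.7 ± 4.21 to 10.5 ± 1.62 CPM (4.79-fold), and REEP3, a protein of the endoplasmic reticulum, from 122 ± 11.4 to 29.3 ± 1.65 CPM (4.13-fold). They were followed by IGFBP7-AS1, the choline transporter SLC44A1, the cholesterol ester hydrolase NCEH1, the secreted protein IGFBP7, the small GTPase RAP1A, the sarcoglycan SGCB and the Golgi protein YIPF6, each lowered by 3.50-fold to 4.00-fold. IGFBP7-AS1 overlaps IGFBP7 on chromosome 4, and their reads may be shared. The largest rise was in TMEM45A, a transmembrane protein gene, from 4.02 ± 0.754 to 26.4 ± 1.54 CPM (6.48-fold). GDF15, a secreted stress-induced member of the TGF-beta family, rose 4.72-fold to 51.6 ± 9.19 CPM. LCP1, an actin-bundling protein, rose 3.49-fold, the hypoxia-induced carbonic anhydrase CA9 3.42-fold, and the retinoic acid binding protein CRABP2 3.24-fold. The rule also named the histone genes H2AC6 and H4C9 and C1QL1, FAM222A and CDC42BPG, with log2 fold changes from 1.45 to 1.69.

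**Figure D2:**
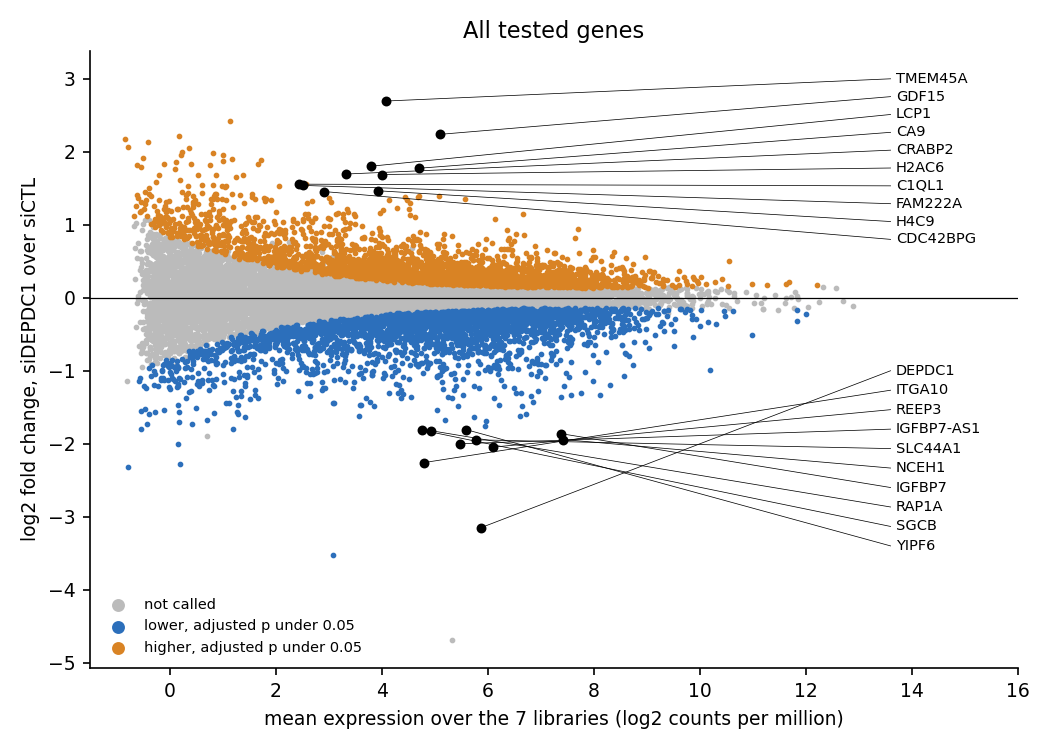
Log2 fold change (siDEPDC1 over siCTL) of each of the 16583 tested genes against its mean log2 CPM over the 7 libraries. Blue and orange points are the 2975 lower and 2732 higher genes, and black points with names are the 10 largest falls and 10 largest rises of the rule, from DEPDC1, down 8.89-fold, to TMEM45A, up 6.48-fold.

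The genes that fell most shared a 3' UTR sequence. The word GATAACT was present in the annotated 3' UTR of 7 of the 8 searched genes among these falls besides DEPDC1 (REEP3, SLC44A1, NCEH1, IGFBP7, RAP1A, SGCB and YIPF6, but not ITGA10) and in none of the 10 largest rises. It was carried by 950 (7.71%) of the 12322 searched genes, but by 83 of the 151 searched genes that were lower at least 2-fold (55.0%) and by 2 of the 156 that were higher at least 2-fold (1.28%). The word was selected by fold change in a random 6161 of these genes, so the counts include genes that selected it. In the 6161 genes not used for this, carriers shifted by -0.28 ± 0.022 (SE) on the log2 scale against other genes. The median log2 fold change was -0.24 in carriers, -0.23 with 1 copy and -0.32 with 2 copies or more, against 0.022 in genes with no copy in the 3' UTR or coding sequence. DEPDC1 itself has the word in its last exon (chromosome 1, 68476930 to 68476936; exon 12 of 12 in transcript DEPDC1-202), within TAGTCTAAGATAACTAACTGAAT. There the word starts before the 3' UTR and spans the stop codon TAA, so it is neither a 3' UTR copy nor a wholly coding copy. The 643 genes with only a coding copy had a median log2 fold change of -0.13. Of these, 35.8% were lower, against 16.4% of genes with no 3' UTR or coding copy. The coding copies were compared without adjustment for coding length or base composition, so this difference cannot be assigned to the word. Carriers here are genes with a copy in a searched 3' UTR. Without them, 137 genes were lower at least 2-fold. Carriers among the genes named in the following paragraphs are marked as such. MUC1, MYC, H2BC12, H1-2 and CASP8AP2, among others, were not searched.

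**Figure D3:**
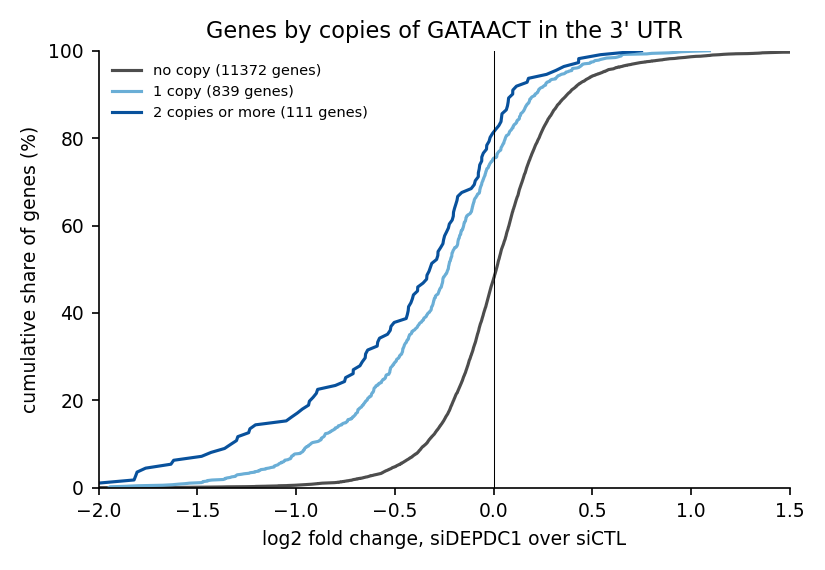
Cumulative share of genes (percent) by log2 fold change (siDEPDC1 over siCTL) for the 11372, 839 and 111 searched genes with no copy, 1 copy and 2 or more copies of GATAACT in the 3' UTR. The curves of the carriers lie to the left of the curve of genes without a copy, with medians of -0.23 for 1 copy and -0.32 for more.

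Genes of mitosis were higher as a group. Of 24 tested members of the list, 17 were higher and 1 lower (18 and 1 adjusted over the list alone), and the median log2 fold change was 0.26 (camera adjusted p = 7.9e-08, higher). With an estimated correlation, 0.38 for this list, the call was lost (camera adjusted p = 0.26). PTTG1, the securin that inhibits separase until anaphase, rose from 116 ± 3.20 to 178 ± 8.75 CPM. KIF20A, a kinesin of cytokinesis, rose 1.48-fold and the spindle kinase AURKA 1.31-fold. CDK1, the kinase that drives entry into mitosis, was lower (156 ± 9.23 to 137 ± 13.0 CPM, edgeR adjusted p = 0.025), a call lost without siCTL replicate 2, siCTL replicate 3 or siDEPDC1 replicate 4 (edgeR adjusted p = 0.096, 0.084 and 0.12). DNA replication and G1/S genes moved both ways, with 8 lower and 5 higher of 25 (9 and 5 adjusted over the list alone; camera adjusted p = 0.086). GINS1, part of the replicative helicase, fell 2.91-fold and RRM1, the large ribonucleotide reductase subunit, 1.52-fold, and both carry GATAACT. The transcription factors E2F1 and E2F2 rose 1.33-fold and 1.41-fold. That list passed the test, as lower, without siCTL replicate 3 (camera adjusted p = 0.029), without siDEPDC1 replicate 3 (0.022) and with no count filter (0.0016), with up to 0.67 under the other alternatives at the preset correlation and 0.76 with an estimated correlation. Among 18 homologous recombination and Fanconi genes, 5 were lower, with EXO1 at -0.38 and the carrier BARD1 at -0.28 on the log2 scale, and RAD51AP1 was higher (camera adjusted p = 0.55, with the same counts adjusted over the list alone).

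Replication-dependent histone genes, whose messenger RNAs normally end in a stem-loop without a poly(A) tail, rose. Of 8 tested members of the list, 6 were higher and none lower (6 and 0 adjusted over the list alone), with a median log2 fold change of 0.90 (camera adjusted p = 5.6e-09, and adjusted p = 0.034 with an estimated correlation). H2BC12 rose from 17.5 ± 1.39 to 45.9 ± 2.22 CPM, H2AC6 from 7.03 ± 0.757 to 22.6 ± 2.63 CPM and the linker histone H1-2 from 13.6 ± 1.35 to 35.6 ± 3.67 CPM. Histone genes of the same class have similar coding sequences, so the counting may have split reads between such genes.

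Genes of glycolysis and hypoxia were higher and genes of fatty acid metabolism lower. In the first list 10 of 20 were higher and 1 lower (10 and 2 adjusted over the list alone; median log2 fold change 0.089, camera adjusted p = 2.1e-06, but adjusted p = 0.26 with an estimated correlation). CA9 rose from 10.8 ± 1.33 to 37.1 ± 2.83 CPM, NDRG1, a hypoxia-responsive gene, 1.77-fold, and PFKFB4, a regulator of glycolytic flux, 1.68-fold, whereas the hypoxia-induced peptide gene ADM fell 1.41-fold. The glycolytic genes LDHA (-0.0078), ENO1 (0.031) and ALDOA (-0.0082) and the glucose transporter SLC2A1 (0.036) did not pass the test. Without the carriers of GATAACT the median of this list was 0.027, and the list stayed called (highest camera adjusted p over all alternatives at the preset correlation 0.00021). In fatty acid metabolism 9 of 20 were lower and none higher (9 and 1 adjusted over the list alone; median -0.14, camera adjusted p = 0.0032, but adjusted p = 0.23 with an estimated correlation). SCD, the stearoyl-CoA desaturase and a carrier of the word, fell from 1629 ± 62.8 to 818 ± 94.4 CPM, ACLY, which makes cytosolic acetyl-CoA, 1.35-fold, and ACADM, a mitochondrial acyl-CoA dehydrogenase, 1.34-fold. Cholesterol genes went both ways, with 4 lower and 4 higher of 21 (the same adjusted over the list alone; camera adjusted p = 0.88). The sterol enzymes SC5D and IDI1, both carriers, fell 1.92-fold and 1.35-fold.

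Antigen presentation genes were lower, with 9 of 16 lower and none higher (10 and 0 adjusted over the list alone), a median log2 fold change of -0.23 and a camera adjusted p of 0.0040. The call was lost with an estimated correlation (camera adjusted p = 0.23). The estimate itself was 0.0096, no higher than the preset 0.01, so a higher correlation does not explain the loss. ERAP1, the aminopeptidase that trims peptides and a carrier of GATAACT, fell 1.37-fold, the peptide transporter gene TAP2 1.24-fold and HLA-B 1.23-fold. HLA class I genes are close paralogs, and their counts may be shared. Of 18 NF-kB targets and cytokines, 8 were lower and 2 higher (the same adjusted over the list alone; camera adjusted p = 0.12). BIRC3 and TRAF1, regulators of TNF receptor signalling, fell 1.61-fold and 1.43-fold, while the cytokine genes LIF and IL1B rose 1.38-fold and 1.47-fold. Of 21 type I interferon response genes, 5 were lower and 1 higher (4 and 1 adjusted over the list alone; camera adjusted p = 0.35). The double-stranded RNA sensors OAS2 and RIGI fell 1.69-fold and 1.28-fold, and IFI6 rose 1.30-fold.

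Among 17 tested mesenchymal and invasion genes, 8 were lower and 3 higher (8 and 4 adjusted over the list alone; median log2 fold change -0.076, camera adjusted p = 0.025, but adjusted p = 0.23 with an estimated correlation). The correlation estimated for this list was 0.0064, also no higher than the preset 0.01. ITGA5, the fibronectin receptor subunit and a carrier of GATAACT, fell from 258 ± 10.3 to 140 ± 10.1 CPM. PLAU, the urokinase gene, fell 1.68-fold and MMP14, a membrane metalloprotease, 1.31-fold, while the transcription factor SNAI2 rose 1.30-fold. The list did not pass the test without the carriers (camera adjusted p = 0.18), nor without siCTL replicate 1, siCTL replicate 2 or siDEPDC1 replicate 2 (camera adjusted p = 0.062, 0.059 and 0.052). It also missed the threshold with the stricter count filter and with limma-voom (camera adjusted p = 0.11 and 0.090). Epithelial genes went both ways, with 4 lower and 5 higher of 15 (4 and 6 adjusted over the list alone; camera adjusted p = 0.75). MUC1, a membrane mucin, fell 2.39-fold, the desmosomal gene DSP 1.31-fold and CDH1, the E-cadherin gene, 2.92-fold from a level of only 1.11 ± 0.378 CPM, and the keratin gene KRT18 rose 1.23-fold. YAP/TEAD targets had 6 lower and 5 higher members of 20 (7 and 5 adjusted over the list alone; camera adjusted p = 0.52). CRIM1, a carrier, fell 2.20-fold, while IGFBP3 rose 1.47-fold and GADD45A 1.46-fold.

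**Figure D4:**
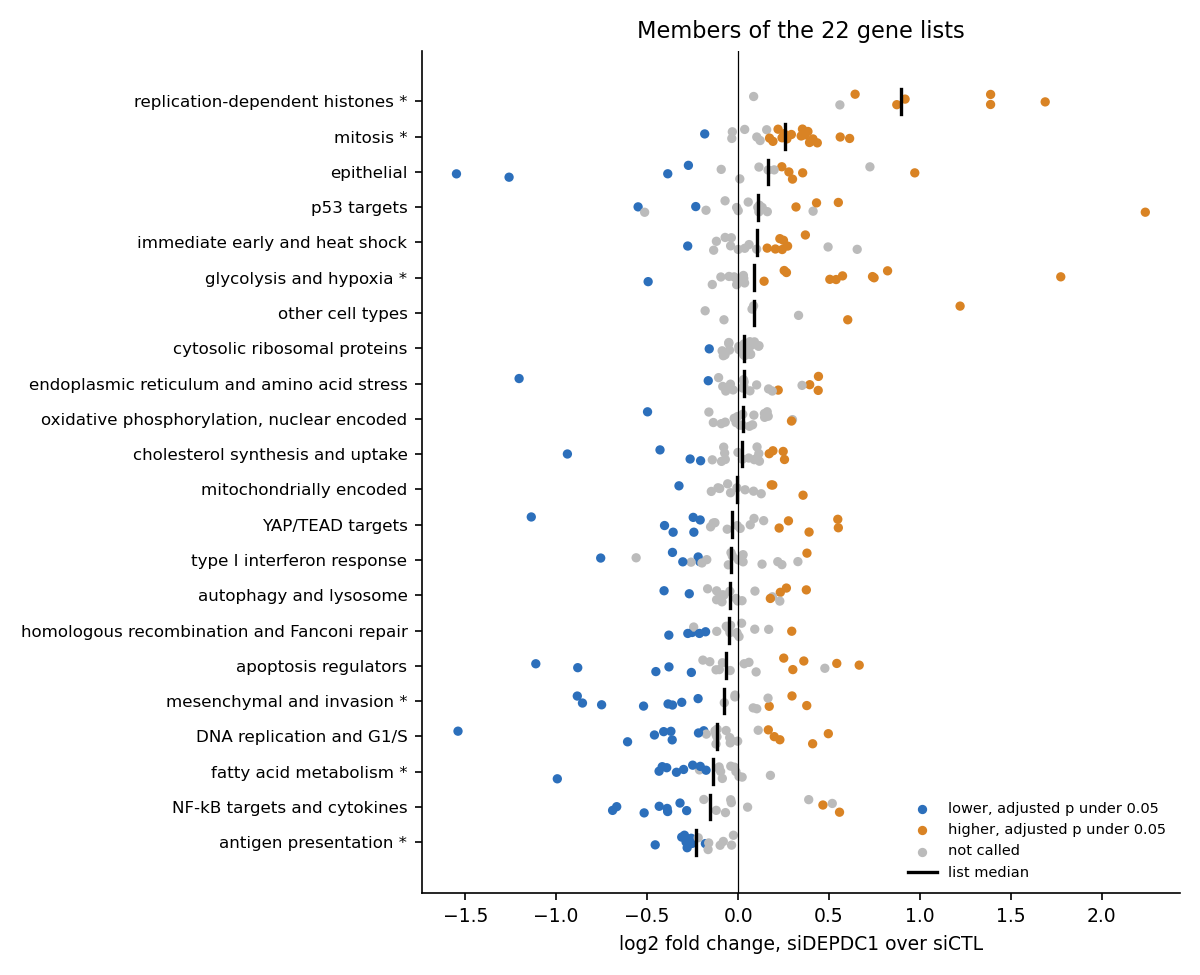
Log2 fold change (siDEPDC1 over siCTL) of every tested member of the 22 gene lists (points; blue lower, orange higher, grey not called), with the median of each list as a black bar and an asterisk on lists called by camera. The replication-dependent histones have the highest median, 0.90, and antigen presentation the lowest, -0.23.

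Of 18 p53 targets, 4 were higher and 2 lower (the same adjusted over the list alone; camera adjusted p = 0.092). GDF15 rose 4.72-fold and the cell cycle inhibitor CDKN1A 1.47-fold, whereas ZMAT3 fell 1.46-fold and the p53 regulator MDM2 had a log2 fold change of 0.056 that did not pass the test. Apoptosis regulators had 5 lower and 5 higher members of 20 (the same adjusted over the list alone; camera adjusted p = 0.18). BAK1, a pore-forming death effector, fell 2.16-fold, and the survival genes MCL1 and CFLAR 1.84-fold and 1.37-fold, all of them carriers of GATAACT, while the pro-apoptotic genes BMF and BAD rose 1.59-fold and 1.28-fold. In the endoplasmic reticulum and amino acid stress list, 2 were lower and 4 higher of 20 (the same adjusted over the list alone; camera adjusted p = 0.82). PSAT1, of serine synthesis, fell 2.30-fold, but PHGDH, of the same pathway, and the cystine transporter SLC7A11 each rose 1.36-fold, the latter as a carrier of the word. Immediate early and heat shock genes had 7 higher and 1 lower members of 19 (the same adjusted over the list alone; camera adjusted p = 0.092), with JUN up 1.29-fold, MYC 1.21-fold and IER2 1.19-fold. That list passed the test, as higher, without siDEPDC1 replicate 1 and with no count filter (camera adjusted p = 0.048 and 0.020), with up to 0.18 under the other alternatives at the preset correlation and 0.67 with an estimated correlation.

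Cytosolic ribosomal proteins had 1 lower of 22 (0 adjusted over the list alone; camera adjusted p = 0.75) and nuclear-encoded oxidative phosphorylation 1 lower and 1 higher of 20 (0 and 1 adjusted over the list alone; camera adjusted p = 0.54). Among 13 mitochondrially encoded genes 1 was lower and 3 were higher (1 and 2 adjusted over the list alone; camera adjusted p = 0.78), with MT-CO3 at -0.32 and MT-ND3 at 0.36 on the log2 scale. Autophagy and lysosome genes had 2 lower and 4 higher of 21 (the same adjusted over the list alone; camera adjusted p = 0.95), with the receptor SQSTM1 down 1.33-fold and ATP6V1H, a proton pump subunit, up 1.30-fold. Of 7 tested markers of other cell types, COL1A1 rose from 12.9 ± 1.35 to 30.2 ± 2.52 CPM and CD14 from 2.06 ± 0.498 to 3.25 ± 0.634 CPM, with none lower (the same adjusted over the list alone; camera adjusted p = 0.092). CD14 lost its call without siCTL replicate 1, siCTL replicate 3, siDEPDC1 replicate 3 or siDEPDC1 replicate 4 (edgeR adjusted p = 0.070, 0.12, 0.061 and 0.11). Median, mean and camera direction differed in sign in 4 uncalled lists. Medians and means were -0.045 and 0.00033 for autophagy and lysosome, -0.0062 and 0.015 for mitochondrially encoded genes, and 0.17 and -0.013 for epithelial genes, each with a camera direction of higher, and 0.024 and -0.039 for cholesterol genes, with a direction of lower.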

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

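Each of 125 sets of 4 siDEPDC1 values (named genes, list means and library measures) was examined for a single library far from the other 3, by the gap to its nearest neighbour as a share of the whole range. Chance flags about 1 in 20 such sets, and 8 (6.4%) passed, so a few of these are expected with no cause, and none was weighed further. In siDEPDC1 replicate 1, E2F1 was low at 93.3 CPM against 111 to 113 in the others (share 0.906). The same library was high in CFLAR, at 40.5 against 37.6 to 37.9 CPM (share 0.885), SLC7A11, at 232 against 183 to 185 CPM (share 0.962), and SC5D, at 17.5 against 11.6 to 12.5 CPM (share 0.842). Its mean log2 CPM of cytosolic ribosomal protein genes was low, at 8.96 against 9.12 to 9.13 (share 0.948). In siDEPDC1 replicate 4, RAD51AP1 was low at 40.7 CPM against 52.1 to 52.4 (share 0.980), as was the mean log2 CPM of the homologous recombination and Fanconi list, at 5.17 against 5.34 to 5.37 (share 0.850). In siDEPDC1 replicate 3, the library with the lowest total, mitochondrially encoded genes took 4.35% of counts against 4.07% to 4.08% (share 0.963). Most of the 8 flags were in siDEPDC1 replicate 1, a clustering that the 1 in 20 rate does not address. On the first principal component that library lay nearest to the siCTL libraries, at 15.0 against 19.6 to 24.1 in the other siDEPDC1 libraries. Without it, 6140 genes were called against 5707 with all libraries. The cause was not tested.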

How the results depend on the processing

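The removal of the GC and length trend and the removal of carriers of GATAACT were chosen after seeing the data. Under all alternatives run, DEPDC1 kept its call, with log2 fold changes from -3.22 to -3.05. Counts of lower and higher genes stayed within 2240 to 3327 and 1991 to 3433. Without 1 library each, lower genes numbered 2462 to 3159 and higher genes 2132 to 2981, and the 2-fold counts 205 to 246 lower and 201 to 277 higher. Genes lower at least 2-fold numbered 357 with no count filter, 126 with the stricter filter, which tests fewer genes, and 137 without the carriers. Genes higher at least 2-fold numbered 54 with the stricter filter. Of the 22 lists, 3 were called lower and 3 higher. These became 6 and 5 with no count filter, where DNA replication, apoptosis and NF-kB lists were also called lower and p53 and immediate early lists higher (the cause was not tested), 0 and 1 with an estimated correlation, where only the histone list stayed called, and 7 and 6 with fry, which does not compare a list with other genes. Among 98 called named genes besides DEPDC1, 15 lost the call under some alternative, 13 of them without 1 library (ATF4, CD14, CDK1, CLDN7, GABARAPL1, MSMO1, MT-CYB, MVK, NDUFB8, OAS3, RPL27, XPC and ZFP36), and none changed sign. Deviations of same-numbered libraries correlated at -0.12, -0.042 and 0.0030, so no shared effect of the replicate number was seen. Libraries of different numbers were not compared in this way, so whether the numbers pair the libraries is not settled. With the replicate block on numbers 1 to 3, 4729 genes were called against 5394 in the same 6 libraries without it; p53 targets were then called higher and NF-kB targets lower (camera adjusted p = 0.047 each; over all alternatives at the preset correlation 0.0048 to 0.19 and 0.043 to 0.24). Thinned to the smallest library, 4451 genes were called, so depth limits the count.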

Other observations

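The gene families in this part, the S phase test, the camera test of the other G2/M genes and the removal of the GC and length trend as an alternative were chosen only after the results were seen. Among 12 gene families defined by symbol, integrins were lower, with 9 of 15 tested lower and 3 higher and a median log2 fold change of -0.41 (camera adjusted p = 2.4e-05, but adjusted p = 0.11 with an estimated correlation). ITGA10 at -2.26 and ITGA5 at -0.88 were among them, and 1 of the 9 carries GATAACT. Cytosolic aminoacyl-tRNA synthetases, which charge transfer RNAs for protein synthesis, were also lower, with 9 of 18 lower and 1 higher (median -0.15, camera adjusted p = 0.00011, but adjusted p = 0.10 with an estimated correlation). TARS1, the threonine enzyme and the carrier in this family, was lowest at -1.33. In the MAGE family, 7 of 11 were higher and 2 lower (median 0.40, camera adjusted p = 0.00017, but adjusted p = 0.093 with an estimated correlation). The higher members were MAGEC2 (1.10), MAGEH1 (0.87), MAGEC1 (0.86), MAGED1 (0.85), MAGED2 (0.62), MAGEE1 (0.40) and MAGEF1 (0.29). Both lower members, MAGEA3 (-0.71) and MAGEA6 (-0.85), were carriers. Collagens went both ways, with 9 higher, COL1A1 and COL7A1 (1.15) among them, and 9 lower of 24 (camera adjusted p = 0.91). The other 8 families, such as kinesins, proteasome subunits, tubulins and keratins, were not called (lowest camera adjusted p = 0.12).

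Of 950 carriers of GATAACT in the 3' UTR, 514 (54.1%) were lower, 79 higher and 357 not called. In the part of the genes not used to find the word, its 487 carriers shifted by -0.28 ± 0.022 (SE) on the log2 scale against other genes of like 3' UTR length, with a one-sided permutation p of 1e-05, the smallest that 100000 permutations can give. Over all 12322 searched genes, the next lowest shift among 420 words of the same bases was -0.14, and the reverse complement shifted by -0.026. These genes include the part used to find the word. In the part not used to find it, the shift was -0.26 after removing the GC and length trend. This argues against such a bias as the whole cause. DEPDC1 has the word followed by A, and carriers with that A had the lowest median, -0.38, but 23.9% of all 7-base words occur in the longest DEPDC1 coding transcript, so its presence there is weak evidence. The values are consistent with seed pairing of the siRNA with other messenger RNAs as a hypothesis; the siRNA sequence, a second siRNA and microRNAs of the same seed were not analysed here, and an effect of DEPDC1 loss itself on any single gene stays open.

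Replication-dependent histone transcripts rose in 10 of the 13 such genes tested, 5 of which averaged at least 5 CPM, with a median log2 fold change of 1.05. For each of 3 explanations the value met the bound set as evidence against it, and each is nevertheless treated as open, for reasons chosen after the values were seen. Other transcripts without a poly(A) tail, which a change in RNA selection would also raise, had a median of -0.11 (bootstrap 95% interval -0.63 to 0.085) with none of 10 called, which argues against it, but 4 are pseudogene copies by name and only 2 averaged at least 5 CPM, neither of which rose: RNU4-5P (0.068 ± 0.15, SE) and RN7SL1 (-4.69 ± 1.86, SE), whose siCTL libraries varied widely (88.4 ± 141 CPM, SD). More cells in S phase would raise the replication list, whose median of -0.12 (bootstrap 95% interval -0.19 to -0.036) stayed below 0 under all alternatives (-0.14 to -0.061), also without carriers of GATAACT, which argues against it, but the list was not called and had 8 members lower and 5 higher. Of 6 genes named for histone 3' end processing (median -0.17), LSM11 (-0.67, a carrier), CASP8AP2 (-0.32) and NPAT (-0.33), chiefly a coactivator of histone transcription, fell, and none rose. SLBP (0.033 ± 0.062, SE), which the test had required to be lower, LSM10 and ZNF473 did not pass the threshold. The median was as low as the explanation required but SLBP was not lower, so these values do not decide whether processing was lowered.

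The mitosis list, whose call was lost with an estimated correlation (adjusted p = 0.26), was compared with 30 other G2/M genes fixed before they were tested, of which 21 were higher and 2 lower, with a median log2 fold change of 0.21 (camera adjusted p = 0.00025, but adjusted p = 0.30 with an estimated correlation). The list's median was 0.32 after removing the GC and length trend and at least 0.24 without any 1 library, so neither such a bias nor a single library accounts for the rise from 0.26. A larger share of cells in G2 and M after DEPDC1 siRNA is consistent with these values as a hypothesis, although CDK1 and, among the other genes, CKAP2 (-0.56) and ARHGAP11A (-0.41), the latter 2 carriers of GATAACT, were lower. Cell cycle phase was not measured, and higher transcription of these genes with no change in phase stays open.

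Of the 35 splits of the 7 libraries into 3 and 4, only 1, the real one, called as many as 5707 genes, a share of 0.0286, the smallest that 3 against 4 libraries allow. Chance assignment of these libraries to the groups can thus be excluded at the 0.05 level, which says nothing of differences between cultures if the libraries did not come from separate ones. The highest other count was 1995, from the split that sets siDEPDC1 replicate 1 with the 3 siCTL libraries, and the next was 4.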
